A study of Mus musculus with 6 samples.

How the data were processed

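Gene expression was measured in hematopoietic stem cells (HSCs) of mouse bone marrow, Cdk6-/- or wild type, untreated or after treatment with polyI:C, a synthetic double-stranded RNA that induces interferon. Per the labels, each of 6 two-colour arrays carried 1 Cdk6-/- sample in Cy5 and a pool of sorted wild-type HSCs of the same treatment in Cy3. The series describes the 3 untreated and the 3 polyI:C-treated samples as biological replicates. Each of the 2 wild-type pools was hybridised 3 times, so it gave 1 control sample per treatment, and its spread is technical. No array had the dyes swapped. A dye bias of a probe therefore cannot be told from a difference between genotypes, but it cancels where the ratio of treated samples is compared with that of untreated samples. The titles of 5 samples hold a pair of numbers, while that of untreated array 3 holds a single number and is written in another style. Whether a pair stands for 2 mice, and how many mice went into a sample or a pool, is not given in the sources used here.

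Per the labels' protocols, total RNA was amplified by whole transcriptome amplification (TransPlex WTA2) and labelled with platinum dyes that bind guanine, with RNA integrity numbers from 5,3 to 8,9. Per the file headers, the arrays were Agilent two-colour arrays, annotated on the mouse assembly mm9 (NCBI37) and read with Agilent Feature Extraction 11.5.1.1. The deposited scanner files hold the median intensity of each spot and of its background, and processed signals, also an intensity, after the software's background subtraction and dye normalization. They also hold a log10 ratio of red to green, deposited beside the signals and used here only to check direction and scale. The flags of the deposited files (other, neither intensity nor ratio) mark control, non-uniform, outlying, saturated and well-above-background spots. The deposited value table is in log2: checked against the scanner files, it differed from the log2 ratio of processed Cy5 to processed Cy3 by at most 2.5e-06, with no further centring. How the authors tested genes is not given in the sources used here.

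The tests, filters, gene lists and most alternatives were fixed before the data were examined. The plan named mean signals; the files hold none, so median signals were used. Signals were background-corrected with normexp (offset 50) and ratios normalized by loess within each array in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Control spots and spots flagged as outlying or non-uniform (0.657% of spots) were left out, and the spots of a probe were averaged. Of 55681 probes, 31802 were tested because they were well above background in Cy5 or Cy3 on all 3 arrays of at least 1 group, and 23879 were left out as dim. A gene with several tested probes (5701 genes) was represented by the probe with the highest mean log2 intensity. This left 22630 genes, 13638 with a symbol and 8992 known only by accession or probe name. Symbols came from RefSeq on GRCm38.p6, where 26391 of 26695 accessions on the probes were matched; probe positions were not remapped.

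Each array held 59305 spots that were not controls. In Cy5, 53.3, 55.7 and 53.7% of spots were well above background on untreated arrays 1, 2 and 3, and 47.0, 51.8 and 76.5% on polyI:C arrays 1, 2 and 3. In Cy3 the shares were 58.0, 58.7, 58.3, 54.4, 56.6 and 75.6% in the same order, and no spot was saturated. Array numbers follow the order of deposition and pair no samples. Both the number of arrays and signal near background limit the precision; with 3 against 3 the smallest exact permutation p is 0.1.

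Genotype was tested on log2 ratios (Cy5 over Cy3) in 1 limma fit (lmFit, eBayes) of all 6 arrays with a mean per group, leaving 4 residual degrees of freedom. This gave the untreated ratio, the polyI:C ratio and the difference of the 2. Treatment within Cdk6-/- samples was tested on log2 Cy5 intensity after loess and quantile normalization of average intensities between arrays. Errors given with log2 values are standard errors of these fits (SE), or standard deviations over 3 arrays where marked SD. Adjusted p-values are limma's, by Benjamini and Hochberg over genes, with a threshold of 0.05. The wild-type pools were compared as values only. Where 1 side of a change was not well above background, the fold is given as "at least", from the brighter side and the dim level.

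Of 27 gene lists fixed in advance, 25 had the 5 measured members needed for a test with camera (limma, preset correlation 0.01), adjusted over lists. They covered interferon response, antigen presentation, S phase, G2 and mitosis, G1 cyclins and CDKs, HSC identity, immediate early genes, p53 targets, NF-kappaB and cytokines, glycolysis, oxidative phosphorylation, ribosomal proteins, Notch, Wnt and TGF-beta signalling, cytokine receptors, markers of 8 other cell types, neighbours of Cdk6 on its chromosome, stress genes and histones. The lists of Xist and of genes on the Y chromosome were too short to test. Beside camera, each list was tested with an estimated correlation and with fry. For the pools, a list's median was ranked among those of 10000 random lists of matched intensity.

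Named genes were Cdk6, the 10 largest rises and falls past the threshold with a symbol and the same sign on all 3 arrays, up to 4 members per list with the smallest p, and genes of the cell cycle and interferon response chosen in advance. Alternatives, whose effect the closing section gives, were no background correction, the deposited processed signals or value table, median centring, other probe filters, every probe or the mean probe of a gene, another prior, slide as a block, array weights, other scalings, a separate-channel model and leaving out each array. Leaving out the 2 arrays low in Xist, leaving out hybridisations of the pools and a slide block for the list tests were added after the data were seen.

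The fits were tested on simulated data with the same spread: 200 of 22505 genes were changed, 50 at each fold. Changes of 2, 4, 8 and 16-fold were recovered in 38, 90, 100 and 100% of genes for the untreated ratio and in 40, 80, 98 and 100% for the polyI:C ratio. For the difference the shares were 10, 72, 90 and 98%, and for treatment 0, 30, 62 and 84%. Genes called without a change were 12 of 176, 6 of 165, 3 of 138 and 3 of 91. The simulated values were independent between genes and between arrays, with no slide effect and no error of the shared pool. These counts therefore do not give the error rate of the real calls. No sample was left out of the fits, and probes without a symbol were tested but not named. The results of some genes are not reported here.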

Results

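HSCs of Cdk6-/- mice were compared with wild-type pools on 6 arrays, untreated and after polyI:C, to ask what the cell cycle kinase CDK6 does when stem cells are activated. Cdk6 itself had 1 probe on the array, and where that probe lies relative to the deleted part of the gene is not known, so it does not check the knockout. Its log2 ratio of Cdk6-/- to wild type was 0.40, -0.41 and 0.24 on the untreated arrays, where Cdk6 was not above background in either channel. On the polyI:C arrays, where both channels were above background, it was -0.26, -0.44 and -1.28 (mean -0.66, SE 0.24, SD 0.54, limma adjusted p = 0.259, n = 3). Cdk6 signal was at least 2.61-fold higher in the treated than in the untreated wild-type pool. In Cdk6-/- samples the signal of this probe was also higher with polyI:C, by 1.23 log2 units from a level not above background.

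The arrays of a group were not alike in sex-linked genes. Xist, transcribed from the inactive X chromosome, had log2 ratios of -3.98 on untreated array 3 and -3.42 on polyI:C array 3, against 1.1 and 0.42 on untreated arrays 1 and 2 and 1.1 and 1.87 on polyI:C arrays 1 and 2. The median ratio of 3 genes of the Y chromosome was 0.61, -0.16 and 1.40 on the untreated arrays and -1.42, -1.15 and 0.65 on the polyI:C arrays. Their median log2 Cy5 signal was 9.60, 10.25 and 10.37 untreated and 8.06, 8.07 and 8.80 after polyI:C (0 of 3 lower over all genes, 3 over the list alone). The sex of the mice is not given in the sources used here. In comparisons between treatments, a difference in sex between the groups therefore cannot be told from polyI:C. PolyI:C array 3 was alone on its slide. Across genes its ratios correlated at 0.13 and 0.22 with those of polyI:C arrays 1 and 2, which correlated at 0.56 with each other. Untreated arrays correlated at 0.49 to 0.54.

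In untreated mice, the immediate early transcription factor Egr1 was higher in Cdk6-/- cells than in the wild-type pool by a log2 ratio of 1.43 (SE 0.18, SD 0.14, adjusted p = 0.00151, n = 3), Nr4a2 by 1.86 (SE 0.23, adjusted p = 0.00158) and Crem, a transcription factor of the cAMP response, by 1.84 (SE 0.31, adjusted p = 0.00579). The Notch ligand Jag2 was higher by 1.45 (SE 0.19, adjusted p = 0.002) and Tapbpl by 1.57 (SE 0.21, adjusted p = 0.002). The proliferation marker Mki67 was lower, at -1.16 (SE 0.20, SD 0.44, adjusted p = 0.00654), as were Cdc25c (-1.47), Kif2c (-1.24) and Foxm1 (-0.94). With median centring in place of loess, Mki67 was at -0.57 (adjusted p = 0.0718) and Foxm1 at -0.50 (adjusted p = 0.0923), neither past the threshold.

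Of 33 genes of G2 and mitosis, 15 were lower over all genes and 21 adjusted over the list alone, none was higher, and the median ratio was -0.64 (camera adjusted p = 4.14e-07; adjusted p = 0.27 with an estimated correlation). The 33 genes of S phase had a median of -0.11 and did not pass (camera adjusted p = 0.905). Among 26 immediate early genes, 5 were higher over all genes and 6 over the list alone, with a median of 0.38 (camera adjusted p = 3.11e-05; adjusted p = 0.6 with an estimated correlation). Of the other kinases, cyclins and inhibitors of G1, the D-type cyclin Ccnd1 was higher at 0.93 (SE 0.24, SD 0.62, adjusted p = 0.0285). That call ended without untreated array 1 (0.90, adjusted p = 0.113) or array 3 (0.64, adjusted p = 0.165). Cdk4 was at -0.02, Ccnd2 at 0.34, Cdkn1a at 0.83 (adjusted p = 0.105), Cdkn1b at -0.33 and Cdkn1c at 0.31, none past the threshold. Cdk2 was lower at -0.70 (SE 0.19, adjusted p = 0.0352) and Ccnd3 at -0.59 (SE 0.16, adjusted p = 0.0406), but with median centring they were at -0.30 (adjusted p = 0.339) and 0.05. Both calls were also lost without any 1 untreated array or polyI:C array 1 or 2. Of the whole G1 list of 21 genes, 1 was higher and 2 were lower, over all genes and over the list alone, and the median was -0.11 (camera adjusted p = 0.959).

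Among the largest ratios below 0 in untreated cells were those of the eosinophil-associated ribonuclease Ear1 (-3.06, SE 0.26, SD 0.49, adjusted p = 0.000476), the lipoxygenase Alox15 (-2.83, SE 0.25, adjusted p = 0.000476), the B cell lectin Siglecg (-2.65, SE 0.27, adjusted p = 0.000649) and the matrix protein decorin, Dcn (-2.44, SE 0.20, SD 0.43, adjusted p = 0.000385). Mid1 (-2.33) and Cemip (-2.28) were also among them, and the leptin receptor Lepr was at least 5.33-fold lower (adjusted p = 0.000476). Ear10 (-2.77), Ear6 (-2.35) and Rnase2a (-2.46) belong to the same near-identical family as Ear1 and are not independent of it. B cell markers were lower in 7 of 15 genes over all genes and 11 over the list alone, with a median of -1.17 (Pax5 -2.19, Cd79b -1.49; camera adjusted p = 1.11e-05; adjusted p = 0.6 with an estimated correlation). Endothelial and stromal markers were lower in 10 of 16 and 12 over the list alone, with a median of -1.05 (Col1a2 -1.43, Acta2 -1.03; camera adjusted p = 4.14e-07; adjusted p = 0.175 with an estimated correlation).

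Granulocyte markers had a median of -0.76, with 7 of 20 lower over all genes and 15 over the list alone (camera adjusted p = 4.54e-06; adjusted p = 0.623 with an estimated correlation), but -0.03 with median centring, which ended the call (adjusted p = 0.0549). Monocyte and macrophage markers had a median of -0.50 (6 of 22 lower, 1 higher, or 8 and 1 over the list alone; camera adjusted p = 0.0247; adjusted p = 0.762 with an estimated correlation), against 0.08 with median centring (adjusted p = 0.142) and -0.34 without untreated array 3 (adjusted p = 0.234). Mast cell and basophil markers were at -0.83 (3 of 8 lower, 5 over the list alone; camera adjusted p = 0.0436; adjusted p = 0.6 with an estimated correlation), a call lost without untreated array 3 (-0.72, adjusted p = 0.234) or polyI:C array 3 (-0.83, adjusted p = 0.0518). Untreated array 3, low in Xist, had the lowest medians for granulocyte markers (-1.53, against -0.59 and -0.37 on arrays 1 and 2) and B cell markers (-1.93, against -1.06 and -0.58).

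In all, 2939 of 22630 genes differed between untreated Cdk6-/- cells and the pool, 691 higher and 2248 lower with loess; with median centring, which moved the median of all genes from -0.05 to 0.30, 6206 differed, 4876 higher and 1330 lower. Counts were 1376, 1630 and 1509 without untreated array 1, 2 or 3. The tests hold the spread between Cdk6-/- samples but not that between wild-type mice, and with no dye swap a bias of a probe towards 1 dye stays in every ratio.

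**Figure D1:**
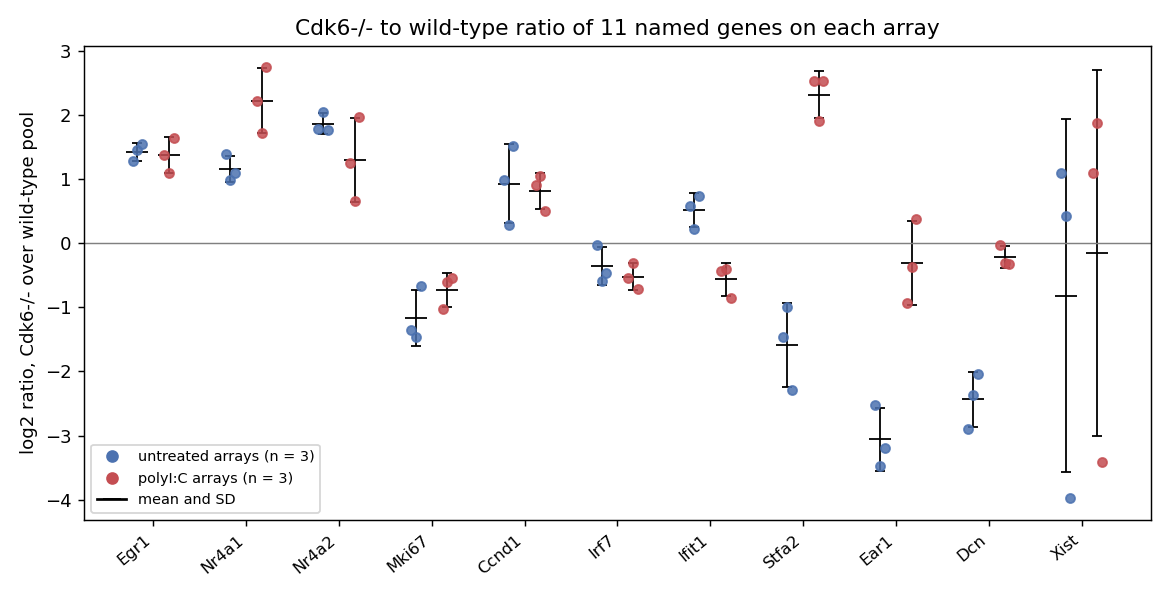
Log2 ratio of Cdk6-/- (Cy5) to wild-type pool (Cy3) for 11 genes on each untreated and polyI:C array. Points are arrays, with the mean and SD over 3 arrays; Egr1 had means of 1.43 and 1.37, and Stfa2 of -1.59 and 2.32.

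After polyI:C, the orphan nuclear receptor Nr4a1, an immediate early gene, was higher in Cdk6-/- cells by a log2 ratio of 2.23 (SE 0.21, SD 0.51, adjusted p = 0.00404, n = 3), a call kept without any 1 array. Egr1 was higher by 1.37 (SE 0.18, SD 0.28, adjusted p = 0.0106) and Zfp36, a protein that destabilizes mRNA, by 1.24 (SE 0.19, adjusted p = 0.0192). Stfa2, a stefin that inhibits cysteine proteases, was higher by 2.32 (SE 0.25, SD 0.36, adjusted p = 0.00647), against -1.59 untreated. Stfa1 (2.40), Stfa3 (1.73), Stfa2l1 (1.76), Cstdc4 (1.51) and Cstdc5 (2.17) are near-identical to it and not independent. The macrophage receptor Marco was higher by 1.75 (SE 0.30, adjusted p = 0.0291). Genes of red cells among those lower were Pklr, the red cell pyruvate kinase, at -2.14 (SE 0.29, adjusted p = 0.013), Car1 at -1.61 (SE 0.22, adjusted p = 0.013), Rhag at -1.68 (adjusted p = 0.0283) and Klf1 at -1.19 (adjusted p = 0.042).

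Immediate early genes were higher in 11 of 26 genes over all genes and 24 over the list alone, with a median ratio of 1.0 (camera adjusted p = 3.77e-27; adjusted p = 0.161 with an estimated correlation). Granulocyte markers had a median of 0.80 (17 of 20 higher and 1 lower over the list alone, 0 over all genes; camera adjusted p = 1.66e-13; adjusted p = 0.208 with an estimated correlation). Monocyte markers had a median of 0.65 (10 higher and 1 lower over the list alone; camera adjusted p = 5.94e-05; adjusted p = 0.533 with an estimated correlation), but 0.34 without polyI:C array 3, which ended the call (adjusted p = 0.0766). Erythroid markers had a median of -0.76, with 3 of 19 lower over all genes and 11 over the list alone (camera adjusted p = 3.65e-12; adjusted p = 0.161 with an estimated correlation).

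Interferon response genes had a median of -0.42, with 1 of 51 lower over all genes, Cmpk2 (-0.92, SE 0.16, adjusted p = 0.0346), and 14 over the list alone (camera adjusted p = 2.79e-12; adjusted p = 0.161 with an estimated correlation). With median centring, which moved the median of all genes to 0.21, the interferon median was 0.23 and the call ended (adjusted p = 0.484), as did that of Cmpk2 (-0.29, adjusted p = 0.44). Ifit1 was at -0.56 and Isg15 at 0.17, neither past the threshold. Genes of S phase had a median of -0.36 (9 of 33 lower over the list alone; camera adjusted p = 1.6e-08; adjusted p = 0.161 with an estimated correlation). With median centring their median was 0.01, below the 0.21 of all genes, and the list was still called as lower. Genes of G2 and mitosis had a median of -0.28 with no member past either threshold (camera adjusted p = 3.91e-05; adjusted p = 0.188 with an estimated correlation); Mki67 was at -0.73 (adjusted p = 0.15). Cdk4 (-0.47), Ccnd1 (0.82), Ccnd2 (0.15), Ccnd3 (0.02), Cdkn1a (0.82), Cdkn1b (0.21) and Cdkn1c (0.85) did not pass.

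In all, 219 of 22630 genes differed after polyI:C, 72 higher and 147 lower. With median centring 2583 did, 2345 higher and 238 lower. Without polyI:C array 1 the count was 7 and without array 2 it was 21. Egr1 was then at 1.37 (adjusted p = 0.118) and 1.51 (adjusted p = 0.0607), and Stfa2 without array 1 at 2.22 (adjusted p = 0.0882). Of the genes named, only Nr4a1 and Mid1 kept their call without each array in turn. Without polyI:C array 3 the count was 218 (24 higher, 194 lower), and without both arrays low in Xist it was 0, with 3516 genes at unadjusted p under 0.05 in limma. Of the genes called, 17 were higher and 127 lower in both treatments, against 2.20 and 14.6 if the calls were independent, and 14 had opposite signs. A dye bias is shared by both treatments, and so is the fit's estimate of each gene's spread. Independence is therefore not the level to expect, and the excess does not by itself show a genotype effect. Among the 127 were Mid1 (-2.33 untreated, -2.06 after polyI:C), Cemip (-2.28, -1.76) and Hpx (-2.03, -1.73).

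**Figure D2:**
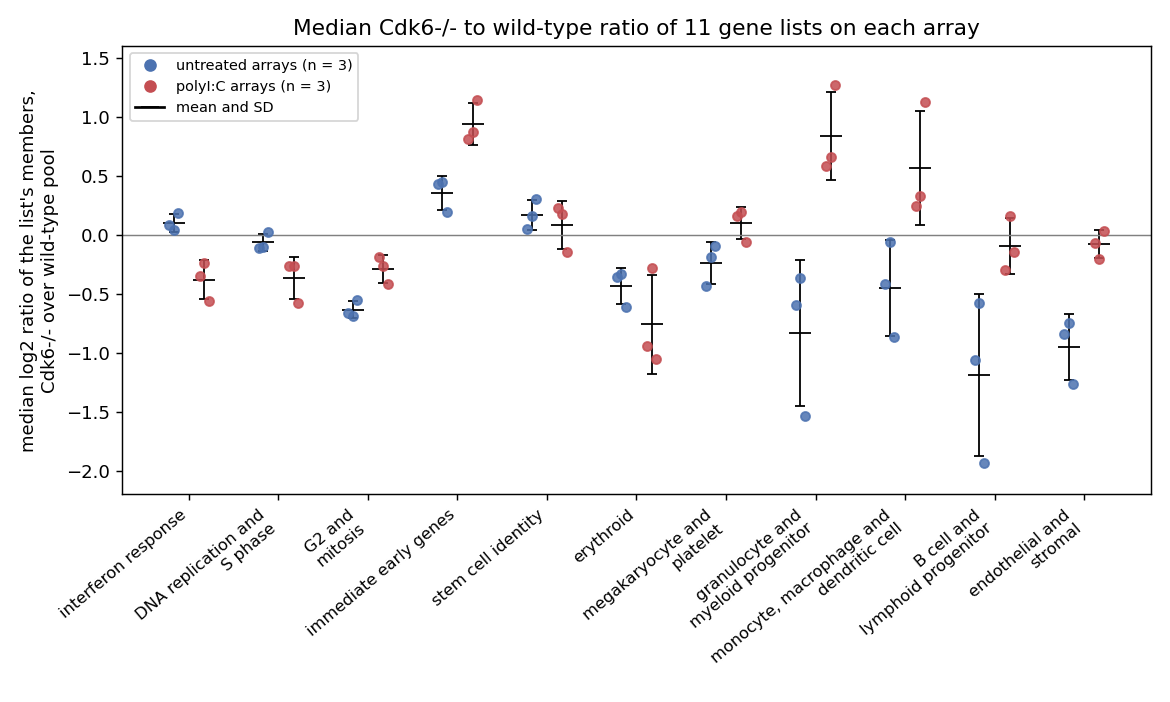
Median log2 ratio of Cdk6-/- (Cy5) to wild-type pool (Cy3) of 11 gene lists on each array, untreated and after polyI:C. Points are arrays, with the mean and SD over 3 arrays.

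Between treatments, the ratio of Cdk6-/- to wild type moved for single genes in both directions. Stfa2 was up after polyI:C by 3.91 log2 units (SE 0.35, adjusted p = 0.00402, 3 arrays against 3) and S100a8, an abundant granulocyte protein, by 2.21. Among other genes, the selenoprotein Gpx3 moved by 2.87 (SE 0.29, adjusted p = 0.00736) and Siglecg by 2.74. Granulocyte markers moved up in 8 of 20 genes over all genes and 18 over the list alone, with a median of 1.61 (camera adjusted p = 1.57e-15; adjusted p = 0.324 with an estimated correlation). Interferon-induced genes among those that moved down were Herc6 by -1.86 (SE 0.28, adjusted p = 0.0171), Iigp1 by -1.32, Ifih1, a sensor of double-stranded RNA, by -1.26 and Eif2ak2, a kinase activated by such RNA, by -1.13. With median centring Iigp1 (-1.04, adjusted p = 0.125), Ifih1 (-1.07, adjusted p = 0.149) and Eif2ak2 (-1.18, adjusted p = 0.0798) did not pass. Of 51 interferon genes, 4 moved down over all genes and 17 over the list alone, with 1 up, and the median was -0.41 (camera adjusted p = 1.5e-11; adjusted p = 0.324 with an estimated correlation).

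Within slides 1 and 2, the only ones with both treatments, Stfa2 moved by 2.90 and 4.41, Gpx3 by 2.36 and 3.02, Herc6 by -1.42 and -2.24, and the interferon median by -0.36 and -0.40. B cell (median 1.24, camera adjusted p = 4.88e-05) and endothelial markers (0.97, camera adjusted p = 5.29e-08) moved up as well; with an estimated correlation adjusted p = 0.324 and adjusted p = 0.146. Immediate early genes moved up by a median of 0.63 (0 of 26 over all genes, 9 over the list alone; camera adjusted p = 5.43e-05; adjusted p = 0.324 with an estimated correlation), while Egr1 did not pass (-0.06, SE 0.25, adjusted p = 0.947). Genes of S phase had a median of -0.39 with no member past either threshold (camera adjusted p = 0.000602, adjusted p = 0.324 with an estimated correlation). Mki67 (0.44), Ccnd1 (-0.11), Cdk4 (-0.45), Isg15 (-0.11) and Ifit1 (-1.08, adjusted p = 0.0675) did not pass.

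In all, the ratio of 406 of 22630 genes differed between treatments, 361 higher and 45 lower after polyI:C. Without polyI:C array 3 the count was 6, none of them named here (Stfa2 3.80, adjusted p = 0.0552; Gpx3 2.82, adjusted p = 0.0552; Herc6 -1.92, adjusted p = 0.0722). Without untreated array 1 or 3, or polyI:C array 1 or 2, it was 177, 67, 100 and 86. With slide as a fixed block it was 0, with 4439 genes at unadjusted p under 0.05 in limma.

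Within Cdk6-/- cells given polyI:C, the chemokine Ccl5 rose by 3.92 log2 units (SE 0.34, adjusted p = 0.0108, 3 arrays against 3), the interferon regulatory factor Irf7 by 3.46 (SE 0.32, adjusted p = 0.0108), the protease Usp18, which removes ISG15 from proteins, by 2.74 (SE 0.31, adjusted p = 0.0186) and Cxcl9 by 2.71 (SE 0.32, adjusted p = 0.0209). The platelet integrins Itga2b (3.14, adjusted p = 0.0496) and Itgb3 (3.03, SE 0.35, adjusted p = 0.0194) rose together. Band 3 of the red cell membrane, Slc4a1, fell (-3.75, SE 0.47, adjusted p = 0.0259), as did Trim10 (-3.04, SE 0.41, adjusted p = 0.0335).

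Of 51 interferon genes, 2 rose over all genes and 25 over the list alone, and the median was 1.1 (camera adjusted p = 1.85e-24; adjusted p = 0.203 with an estimated correlation). Ifit1 (2.49, adjusted p = 0.191), Isg15 (1.58) and Ly6a (1.44) were not past the threshold. Megakaryocyte and platelet markers rose by a median of 1.30 (2 of 18 over all genes, 11 over the list alone; camera adjusted p = 2.63e-12; adjusted p = 0.0661 with an estimated correlation). T and NK cell markers, among them Ccl5, rose by 1.11 (1 of 16, 8 over the list alone; camera adjusted p = 9.91e-09; adjusted p = 0.0661 with an estimated correlation). Erythroid markers fell, with a median of -1.43 (3 of 19 over all genes, 12 lower and 1 higher over the list alone; camera adjusted p = 2.63e-12; adjusted p = 0.203 with an estimated correlation). B cell markers fell as well, with a median of -1.05 (0 of 15 over all genes, 2 over the list alone; camera adjusted p = 1.57e-08; adjusted p = 0.254 with an estimated correlation), and so did endothelial and stromal markers, at -0.50 (0 of 16, 5 over the list alone; camera adjusted p = 0.000374; adjusted p = 0.203 with an estimated correlation). Genes of G2 and mitosis had a median of 0.46 with no member past either threshold (camera adjusted p = 0.00308; adjusted p = 0.422 with an estimated correlation), and 0.33 without polyI:C array 2, which ended the call (adjusted p = 0.0661). Genes of S phase were at -0.00 and Mki67 at -0.12; without polyI:C array 3 the S phase median was 0.31 (adjusted p = 0.048). HSC identity genes had a median of -0.31 (camera adjusted p = 0.0311; adjusted p = 0.58 with an estimated correlation), a call lost without untreated array 3 (-0.25, adjusted p = 0.165) or polyI:C array 3 (-0.16, adjusted p = 0.264), and with slide as a fixed block (-0.21, adjusted p = 0.361). Procr, a surface marker of stem cells, was at -2.48 (adjusted p = 0.106). Replication-dependent histones, a list filed in advance under RNA quality, moved with treatment as well, by a median of 0.28 (0 of 11 over all genes, 2 over the list alone, camera adjusted p = 0.0301, adjusted p = 0.58 with an estimated correlation). Whether they follow RNA quality here was not tested. That call was lost without untreated array 3 (0.23, adjusted p = 0.251) or polyI:C array 1 (0.15, adjusted p = 0.149) or 2 (0.24, adjusted p = 0.136).

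In all, 37 of 22630 genes changed, 24 up and 13 down. Without untreated array 1, 2 or 3, or polyI:C array 1, no gene passed limma (1750, 1669, 2145 and 1699 genes at unadjusted p under 0.05). Each call on a single gene in this comparison was therefore lost without any 1 of these 4 arrays, while Ccl5, for example, stayed between 3.77 and 4.15.

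The wild-type pools were compared by values alone (1 RNA sample per treatment, hybridised 3 times). Cxcl10 was higher in the treated pool by 4.64 log2 units, Irf7 by 3.62, Ccl5 by 3.76 and Ifit1 by 3.57; in Cdk6-/- cells the same genes were higher by 3.46, 3.46, 3.92 and 2.49. The interferon median was 1.67 in the pools, above every random list, and 1.1 in Cdk6-/- cells. Markers of several other cells were lower in the treated pool: B cell markers had a median of -2.56 (14 of 15 without overlap of the hybridisations), granulocyte markers of -1.90 (17 of 20) and endothelial and stromal markers of -1.86, all below every random list, against -1.05, -0.14 and -0.50 in Cdk6-/- cells. Ear1 was at -3.69 in the pool and -0.94 in Cdk6-/- cells, and Siglecg at -3.59 and -0.86. Immediate early genes were lower in the treated pool, with a median of -0.70, and at -0.19 in Cdk6-/- cells (camera adjusted p = 0.0503, not past the threshold). Megakaryocyte markers were higher by 0.92, T and NK cell markers by 0.56 (8 of 16 higher and 2 lower without overlap), and erythroid markers lower, at -1.21. Genes of S phase had a median of 0.33 in the pools (percentile 99.8 among random lists), with 12 of 33 higher and 4 lower without overlap. In Cdk6-/- cells their median was -0.00, or 0.31 without polyI:C array 3. Genes of G2 and mitosis were at 0.14 in the pools (percentile 87.1, 7 higher and 7 lower), against 0.46 in Cdk6-/- cells. Among single genes in the pools, Mki67 was at -0.56, Cdk4 at 1.0, Cdkn1c at -2.40, Cdkn1b at -0.79, Ccnd1 at -0.09 and Egr1 at -0.04.

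Between pools, 9555 of 22630 genes (42.2%) did not overlap between hybridisations, against 10% by chance. By at least 2-fold, 912 were higher and 1805 lower. With the processed signal scaled at its 75th percentile the counts were 1905 and 2431. The spread behind these counts is technical, and polyI:C array 3 was on a slide of its own.

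**Figure D3:**
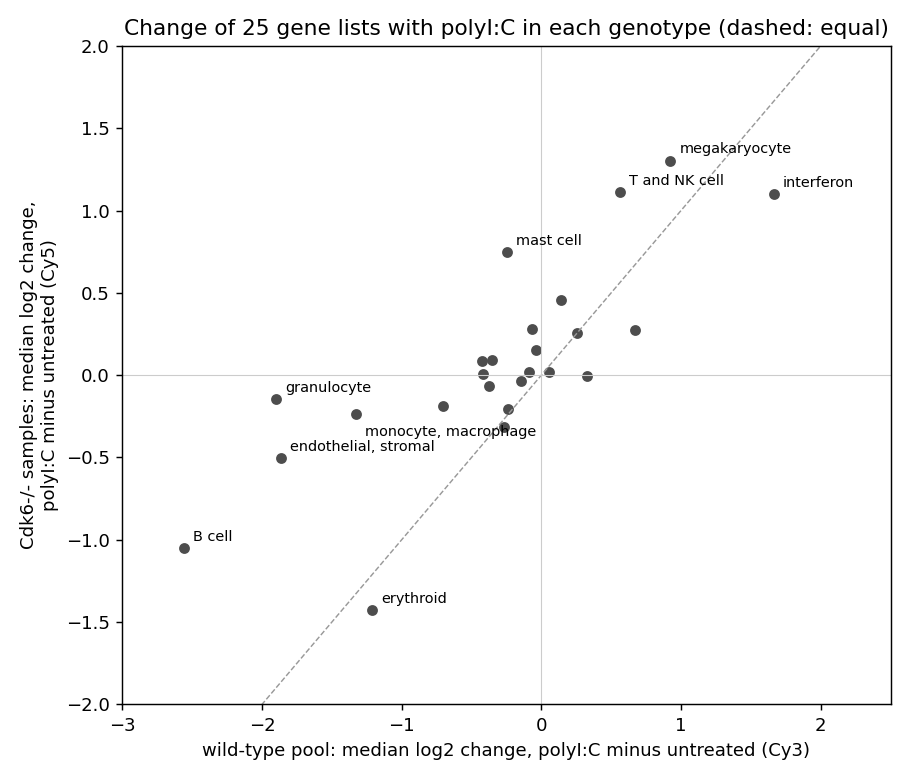
Median log2 change with polyI:C of 25 gene lists in Cdk6-/- cells (Cy5, y axis) against the wild-type pools (Cy3, x axis). Each point is 1 list and the dashed line marks equal change.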

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

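All tests of explanations in this part were chosen only after the results were seen; the splits of the arrays into other groups of 3 were planned before. What marked each result here is a tested difference between treatments in the ratio of Cdk6-/- to wild type. This held for 406 genes, for 13 gene lists and for the genes named below.

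Lists whose ratio moved up after polyI:C, by the median difference of log2 ratios, were granulocyte markers (1.61), B cell markers (1.24), mast cell and basophil markers (1.1), monocyte and macrophage markers (1.0), endothelial and stromal markers (0.97), immediate early genes (0.63), histones (0.43), NF-kappaB and inflammatory cytokines (0.39) and G2 and mitosis (0.29). A ratio also rises where signal falls in the pool. With polyI:C, granulocyte medians changed by -1.90 in the pools and -0.14 in Cdk6-/- cells. Monocyte medians changed by -1.33 and -0.24, and immediate early medians by -0.70 and -0.19. B cell and endothelial markers also fell in both, more in the pools. Mast cell (-0.24 and 0.75), NF-kappaB (-0.35 and 0.09) and histone (-0.07 and 0.28) medians fell only in the pools. G2 and mitosis rose in both (0.14 and 0.46). Lists whose median moved down were erythroid markers (-0.52), interferon response (-0.41), S phase (-0.39) and antigen presentation (-0.31). No member of the S phase, antigen presentation or histone lists passed either threshold, and of the erythroid markers 0 passed over all genes and 1 over the list alone. With an estimated correlation the lowest adjusted p of any of them was 0.146, for endothelial and stromal markers. Within slides 1 and 2 the erythroid median was 0.11 and -0.81, antigen presentation -0.06 and -0.29, monocyte markers 0.27 and 0.92, and mast cell markers 0.44 and 1.15. With median centring antigen presentation was at -0.14 and did not pass (camera adjusted p = 0.286). With slide as a fixed block antigen presentation (-0.20, camera adjusted p = 0.0764) and NF-kappaB (0.29, camera adjusted p = 0.0809) did not pass. Leaving out 1 array ended the calls of G2 and mitosis (0.28 without untreated array 2, 0.24 without polyI:C array 1), mast cell markers (1.17 without untreated array 3, 1.06 without polyI:C array 3), histones (0.37 without untreated array 3, 0.31 without polyI:C array 1, 0.34 without polyI:C array 2) and, without polyI:C array 3, antigen presentation (-0.23), NF-kappaB (0.22) and erythroid markers (-0.26).

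Among genes, the near-identical stefins moved up together: Stfa2 (3.91), Cstdc4 (3.20), Stfa2l1 (3.18), Stfa1 (3.08) and Cstdc5 (3.07). Other genes that moved up were Marco (3.14), Slc11a1 (2.75), Ear1 (2.75), Fcnb (2.41), Chil3 (2.39), S100a8 (2.21), Lyz2 (2.18) and Mmp8 (2.16). So did Siglecg (2.74), Cd79b (1.65), Ppbp (2.06), Itgb3 (1.62), Lepr (2.30) and Dcn (2.22). Gpx3 (2.87), Ptgs2 (1.93), Id3 (1.89), Id2 (1.56) and P4ha1 (1.40) moved up too. Genes that moved down were Adgra3 (-1.99), Slf2 (-1.91), Herc6 (-1.86), Tapbpl (-1.74), Med14 (-1.63), Hoxc4 (-1.60), Ehd3 (-1.55), Atp1b2 (-1.45), Slc38a5 (-1.44), Fundc1 (-1.38), Iigp1 (-1.32), Ifih1 (-1.26) and Eif2ak2 (-1.13). The values of Lepr, P4ha1, Ptgs2 and Hoxc4 are only rough, since at least 1 of the 4 signals behind each was not above background on any array.

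Untreated ratios had medians of -0.76 for granulocyte, -0.50 for monocyte, -1.17 for B cell and -1.05 for endothelial and stromal markers (adjusted p = 0.623, adjusted p = 0.762, adjusted p = 0.6 and adjusted p = 0.175 with an estimated correlation). A dye bias of the probes would be the same after polyI:C, but the median ratio of the 73 members of 4 marker lists was then 1.16 higher (SE 0.30). The 4 lists were flagged by that same difference, so this is no separate test of dye bias. RNA of other cells in the untreated pool, which the labels call sorted HSCs, stays open. Granulocyte markers were bright in both genotypes: S100a9, Lcn2 and Ngp had mean log2 signals of 16.2, 16.1 and 15.9 in the untreated pool. In untreated Cdk6-/- samples they were at 15.2, 15.4 and 15.1, so the same question is open for those samples. After polyI:C they were at 14.4, 14.2 and 13.4 in the pool and at 15.4, 15.3 and 14.5 in Cdk6-/- samples. Of the 10 markers brightest in the untreated pool 9 had an untreated ratio below 0. They were picked from lists already known to be low and by their level in that pool, so this decides nothing. With median centring the untreated medians of granulocyte and monocyte markers were -0.03 and 0.08, and no biological explanation was tested.

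Of 26 immediate early genes, 5 were higher in untreated Cdk6-/- samples and 11 after polyI:C over all genes, with medians of 0.38 and 1.0 (adjusted p = 0.6 and adjusted p = 0.161 with an estimated correlation). After polyI:C the median ratio was 0.58 higher (SE 0.13) than untreated, while a dye bias would be the same in both. The list was flagged by that same difference, so this is no separate test of dye bias. The part seen in both treatments, 0.36 on the untreated arrays (SE 0.08), cannot be told from dye bias without a dye swap. RNA of granulocytes and monocytes in untreated Cdk6-/- samples could also raise such genes and needs their markers above 0, but those were at -0.67 (SE 0.30, 42 members), with 0 of 20 granulocyte and 5 of 22 monocyte markers above 0. This does not decide it for untreated samples, since -0.67 is within 3 SE of 0 and the medians were -0.03 and 0.08 with median centring. After polyI:C, granulocyte markers had a median of 0.80 (19 of 20 above 0) and monocyte markers of 0.65 (16 of 22 above 0). For the excess after polyI:C, RNA of granulocytes and monocytes in the Cdk6-/- samples therefore stays open.

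Of 51 interferon genes, 4 had a lower ratio of Cdk6-/- to wild type after polyI:C than untreated, over all genes, and the median moved by -0.41 (adjusted p = 0.324 with an estimated correlation). With slide as a fixed block the difference of the array medians was -0.39 (SE 0.09), with -0.28 on slide 1 and -0.48 on slide 2. Without polyI:C array 3 it was -0.40 (SE 0.07). That array was alone on its slide and adds nothing to the blocked difference, so both values rest on the same arrays. The difference thus stayed below 0 without that array and within slides 1 and 2, which held 2 and 3 arrays. The list was flagged by this same difference, so these are no separate tests of slides or of that array. The difference also holds the untreated ratios, with a median of 0.09 (6 of 51 higher and 1 lower), against -0.42 after polyI:C. Levels in the untreated samples or the untreated pool are therefore part of it. A weaker interferon response of Cdk6-/- cells could give the lower ratio after polyI:C. So could a pool from mice that had responded more strongly or had been taken at another time. With 1 pool per treatment these cannot be told apart.

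The arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. Of these splits, 1 gave as many genes as the real 406 for the difference, the real one itself, and the highest other gave 2. For lists 2 gave as many as the real 13, since the highest other also gave 13. For treatment in Cdk6-/- cells 1 gave as many as the real 37 genes, with 0 in the highest other, and for lists 2 gave as many as the real 12, the highest other giving 12. Wrong splits mix the 2 treatments, which widens the spread within groups, so few gene calls in them say little.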

How the results depend on the processing

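All alternatives here were chosen before the data were examined except those without the 2 arrays low in Xist, the slide block for lists and the left-out hybridisations of the pools. The cause of each change below was not tested, except that fewer arrays or a block leave fewer residual degrees of freedom. The counts moved with the number of arrays, the filter on dim probes, scaling and weights, though not in every comparison. No paired analysis was possible because the titles give no replicate number shared by the groups. The deposited value table could not be used for treatment within Cdk6-/- samples, since it holds ratios only.

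For the untreated ratio (2939 genes, 691 higher and 2248 lower), median centring gave 6206 (4876 and 1330), processed signals 2515 (321 and 2194; median of all genes -0.20), the deposited ratios 1948, the 3 arrays alone 1770, and the arrays without the 2 low in Xist 1638. Leaving out 1 array gave 1376 to 3426. For the polyI:C ratio (219; 72 and 147), median centring gave 2583 (2345 and 238), processed signals 32 (6 and 26; median of all genes -0.16), the deposited ratios 33, no filter 94, an intensity trend with a robust prior 431, array weights 5769, the 3 arrays alone 84, scale normalization 489 and the arrays without the 2 low in Xist 0. Leaving out 1 array gave 7 to 218.

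For the difference (406), processed signals gave 166, median centring 241, the deposited ratios 184, no filter 253, probes above background in both channels 263, trend and robust prior 645, array weights 2085, slide as a fixed block 0 and the arrays without the 2 low in Xist 0 (4553 genes at unadjusted p under 0.05 in limma). Leaving out 1 array gave 6 to 378. For treatment in Cdk6-/- samples (37; 24 and 13), median centring gave 65 (30 and 35), no filter 16, probes above background in both channels 14, trend and robust prior 101, slide as a random block 126, array weights 589, slide as a fixed block 17, the 75th percentile of processed signals 6 (6 and 0), quantile normalization 50 (27 and 23), the separate-channel model 834 and the arrays without the 2 low in Xist 0 (4129 at unadjusted p under 0.05 in limma). Leaving out 1 array gave 0 to 23.

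Numbers of lists called under a setting count all lists, also those not called at first. For the untreated ratio 11 lists were called, against 0 with an estimated correlation, 2 with fry, 6 without the arrays low in Xist and 6 to 11 leaving out 1 array. For the polyI:C ratio 12 were called, against 0 with an estimated correlation, 6 with fry and 11 to 12 leaving out 1 array; without polyI:C array 3 only 9 of the first 12 were among the 11. For the difference 13 were called, against 0 with an estimated correlation, 3 with fry (2 of them among the first 13), 8 without the arrays low in Xist and 9 to 13 leaving out 1 array. For treatment 12 were called, against 0 with an estimated correlation, 3 with fry and 8 to 13 leaving out 1 array; the 13, without untreated array 2, held all of the first 12 and 1 more. With median centring 10 lists were called for the untreated ratio (9 of the first 11) and 14 for the difference (12 of the first 13). For the polyI:C ratio 15 were called (9 of the first 12), 12 up and 3 down against 7 and 5. The lists for treatment were not tested with median centring. With quantile normalization of the Cy5 channel alone, 15 lists were called for treatment (all of the first 12). Between pools, 2717 genes passed 2-fold without overlap, 4336 with the 75th percentile, and 2753 to 2993 leaving out 1 array of hybridisations.

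With median centring the untreated ratio of Ccnd3 turned to 0.0499 and of Eno1 to 0.24, and the polyI:C medians of antigen presentation to 0.57 and of oxidative phosphorylation to 0.45. The S phase median for treatment (-0.00) was -0.15 to 0.31 leaving out 1 array, turning to 0.31 without polyI:C array 3, and 0.31 without the 2 arrays low in Xist. No other call of a named gene or list turned its direction by its test. Leaving out 1 array kept the side of the threshold of 446 gene results and ended 129 calls for the untreated ratio, 167 and 91 for polyI:C, 173 and 139 for the difference, and 104 and 118 for treatment. Other settings kept 1125 and ended 180, 466 and 119, 568 and 148, and 452 and 83.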

Other observations

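No hypothesis beyond those weighed above was tested; the lists in this part were chosen before the results were seen.

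HSC identity genes had a median untreated ratio of 0.20 (2 of 35 higher, 1 lower over all genes; camera adjusted p = 0.00945; adjusted p = 0.623 with an estimated correlation), but 0.05 without untreated array 3 (adjusted p = 0.0877). Their median after polyI:C was -0.00, with a mean of 0.10, and did not pass (camera adjusted p = 0.138). Mllt3, a regulator of stem cell maintenance, was higher in untreated Cdk6-/- cells at 0.75 (limma adjusted p = 0.0192), as was Vwf at 0.75, while Tek was lower at -0.75; each of these calls was lost without untreated array 1, 2 or 3, where Mllt3 was at 0.63 to 0.85, Vwf at 0.55 to 0.88 and Tek at -0.91 to -0.48. The call of Tek was also lost without polyI:C array 1 or 2 and with median centring (-0.35, adjusted p = 0.304). Ribosomal protein genes had medians of 0.19 untreated (camera adjusted p = 0.000736; adjusted p = 0.762 with an estimated correlation) and 0.21 after polyI:C (camera adjusted p = 3.82e-06; adjusted p = 0.533 with an estimated correlation; 0.09 and not called without polyI:C array 1), with 1 member, Rps6, past the threshold over all genes untreated, a call lost without any 1 untreated array, and 0 after polyI:C. Oxidative phosphorylation genes were at -0.11 untreated (camera adjusted p = 0.585) and -0.15 after polyI:C (camera adjusted p = 0.00313; adjusted p = 0.533 with an estimated correlation; 0.45 with median centring, and -0.09 and not called without polyI:C array 3). Genes of glycolysis were at -0.17 and -0.00, neither called.

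Interferon response genes had a median untreated ratio of 0.09 (6 of 51 higher, 1 lower; camera adjusted p = 0.0307; adjusted p = 0.717 with an estimated correlation), with Herc6 at 1.15. Irgm1 was at 0.83, a call lost without untreated array 1 (0.73) or 3 (0.84). Ifi27l2a was at -1.21, a call lost without untreated array 1 (-1.20) or 3 (-0.78) and with median centring (-0.61). The list's median was 0.03 without untreated array 3 and 0.09 without polyI:C array 3, and not called (adjusted p = 0.0898 and adjusted p = 0.0518). Antigen presentation genes were at 0.19 untreated (camera adjusted p = 0.0307; adjusted p = 0.6 with an estimated correlation; not called without untreated array 1, at 0.14, or array 3, at 0.19) and -0.20 after polyI:C (camera adjusted p = 0.463; 0.57 with median centring). In Cdk6-/- cells they were at 0.27 with polyI:C (camera adjusted p = 0.0157; adjusted p = 0.303 with an estimated correlation; not called without polyI:C array 1, at 0.23, or array 2, at 0.18) and in the pools at 0.67. After polyI:C, p53 targets had a median ratio of 0.22 (camera adjusted p = 0.000694; Tnfrsf10b 0.86), NF-kappaB genes 0.23 (camera adjusted p = 0.00269) and genes of Notch, Wnt and TGF-beta signalling 0.21 (camera adjusted p = 0.00602; Id3 1.42); with an estimated correlation adjusted p = 0.207, adjusted p = 0.207 and adjusted p = 0.161. The NF-kappaB call ended without polyI:C array 3 (0.10, adjusted p = 0.0545) and the Notch call with median centring (0.42, adjusted p = 0.0606).

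The other lists passed in neither ratio. Untreated and after polyI:C, the medians were -0.04 and -0.08 for cytokine receptors, -0.24 and -0.14 for neighbours of Cdk6 on its chromosome, -0.01 and 0.12 for stress genes, -0.26 and 0.24 for histones, -0.34 and 0.05 for T and NK cell markers, and -0.11 and 0.06 for megakaryocyte markers. Untreated medians of p53 targets, NF-kappaB genes and Notch, Wnt and TGF-beta genes were 0.03, -0.21 and -0.12, and that of erythroid markers -0.41 (camera adjusted p = 0.104), none called. After polyI:C the G1 list was at 0.02 (1 of 21 higher over all genes, Btg2 at 1.12, a call lost without untreated array 3 or any 1 polyI:C array), mast cell markers at 0.16, B cell markers at 0.05 with a mean of -0.09, and endothelial markers at -0.09, none called. In Cdk6-/- cells polyI:C left granulocyte markers at -0.14, the G1 list at 0.02 and ribosomal proteins at 0.02, and mast cell markers at 0.75 (camera adjusted p = 0.0506), none called, while monocyte markers were at -0.24 (camera adjusted p = 0.000764; adjusted p = 0.422 with an estimated correlation). Oxidative phosphorylation genes were at 0.25 with polyI:C in these cells (0 of 33 past the threshold; camera adjusted p = 0.0105; adjusted p = 0.596 with an estimated correlation), a call lost without polyI:C array 1 (0.30, adjusted p = 0.119) or 2 (0.18, adjusted p = 0.231). Ddx3y, a gene of the Y chromosome, had an untreated ratio of 1.07 (limma adjusted p = 0.0462), a call lost without untreated array 1 (1.06), 2 (1.25) or 3 (0.91) or polyI:C array 1 (1.07). With the sex of the mice not given, this ratio cannot be told from a difference in sex between the samples and the pool.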
